A study of Homo sapiens with 12 samples.

How the data were processed

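Poly(A) RNA of human glioblastoma cells was sequenced as 12 strand-specific libraries, per the labels' protocols. T98G and U251, 2 established lines derived from glioblastoma, each gave 3 libraries labelled Si and 3 labelled NC. The labels do not spell out either abbreviation; the series text describes cells with NSUN3 knocked down and wild-type cells of both lines, and Si was read as the knockdown and NC as its control. Libraries were placed in the 4 groups T98G_Si, T98G_NC, U251_Si and U251_NC by their titles, and columns of the table were matched to libraries by the names the labels give them.

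The authors deposited raw read counts per gene for the 12 libraries in 1 table, with FPKM and CPM beside them. Tools named in the submitters' processing notes are fastp 0.23.4, HISAT2 2.2.1, featureCounts 2.0.6 and edgeR 4.0.16, with the human build hg38; the notes used here give names and versions only, without settings, and the gene annotation is not given in the sources used here. The deposited counts were whole numbers and were analysed as they stand. The deposited FPKM matched counts divided by gene length and library total within 0.00563 of the ratio. The deposited CPM column, a signal that the authors scaled, matched counts divided by a library total times a TMM factor computed over all listed genes, with the factors equal within 0.000103. The table listed 16540 genes, all typed as protein coding, and 14 symbols were shared by more than 1 of them. Lines whose values were cleared before the table was passed on numbered 2, and these genes are not analysed here. How reads that match several places or overlapping genes were assigned is not given in the sources used here, so near-identical copies and overlapping genes are uncertain.

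Library totals ran from 16069499 to 19288690 counts, and 14276 to 14603 genes had at least 1 count. Counts were compared between replicates with a chi-square statistic over genes with a summed count of at least 20; it lay between 5.35 and 42.1 per degree of freedom, so no pair of libraries agreed within sampling noise and each was kept as 1 replicate. The labels do not state that replicates came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

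Differential expression was computed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, which left 12504 genes, and a quasi-likelihood fit with robust dispersion over the 4 groups with 8 residual degrees of freedom. The common biological coefficient of variation was 0.0992. From this 1 fit came 5 contrasts: Si against NC in T98G, Si against NC in U251, the difference of these effects, their mean, and NC libraries of U251 against NC libraries of T98G. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05 and no minimum fold. Group values are given as mean ± SD of TMM-normalized CPM over 3 libraries, and log2 fold changes with their standard errors (SE). Coordinates are those of GENCODE release 29 on the same human build, 1-based.

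Before the data were examined, 44 gene lists were fixed from textbook knowledge, and camera from limma 3.58.1 tested the 40 lists with at least 5 tested members, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of 1 contrast. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. With the correlation between members estimated from the residuals, no list passed 0.05 in any of the 5 contrasts, and that adjusted p is printed beside each list. Markers of leukocytes, endothelial cells, neurons and oligodendrocytes were among the lists. The rule for genes named in the text was also fixed then: for each Si against NC contrast NSUN3, the 10 largest rises and falls past the threshold with a mean of at least 5 CPM and no overlap between groups, the 3 members with the smallest p of each list past camera, and a panel of NSUN3 and 15 genes on tunneling nanotubes, mitochondria and stress; for the other contrasts the 6 or 8 largest in each direction. Other genes are named as members of a described list, chosen after their values were seen.

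The gene tests and the list tests were tried on simulated counts, with 200 genes changed by known folds for the gene tests. For the T98G contrast 66.7% of genes changed 1.5-fold and 89.6% of genes changed 2-fold were recovered, for U251 64.2% and 95.5%. For the difference between lines 25.4% and 70.1% were recovered, and 4.52% to 6.56% of calls on simulated counts were false. The simulated counts were independent, with 1 spread per gene for both lines and no library set apart from its group. These shares therefore do not measure errors in the real fit, where U251 replicates scattered more than those of T98G. Alternatives tried were RLE and upper-quartile factors, no filter on low counts, a minimum of 1 CPM, DESeq2 1.42.0, limma-voom, a fit of each line alone, a replicate block, a minimum log2 fold of 1, limma-trend on the deposited FPKM and CPM with pseudocounts of 1 and 0.1, and each library left out in turn. No scaling beyond library totals, and a pair of U251 libraries left out together, were added after the data had been seen. Chance was assessed by refitting other splits of the same libraries.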

Results

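Poly(A) RNA was sequenced from T98G and U251, 2 established human glioblastoma lines, in 12 libraries that fall into 4 groups of 3: T98G_Si, T98G_NC, U251_Si and U251_NC. The Si libraries were read as cells in which NSUN3 had been knocked down and the NC libraries as their controls, so the design asks how lowering this enzyme changed the transcriptome of each line and whether both lines responded alike. Library totals ran from 16069499 counts in T98G_Si replicate 3 to 19288690 in T98G_NC replicate 3, and 12504 genes were tested. Adjusted p denotes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and camera adjusted p a test of a gene list against all other genes. Values of groups are mean ± SD (n = 3 libraries) in normalized CPM.

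NSUN3 (ENSG00000178694; chromosome 3, 94062916 to 94128545, hg38), a methyltransferase that places 5-methylcytosine on the mitochondrial tRNA for methionine, was lower in each Si library than in any NC library of its line. In T98G the libraries labelled Si held 94, 80 and 94 NSUN3 counts in replicates 1, 2 and 3, and those labelled NC held 227, 242 and 254. In U251 they held 74, 85 and 75 against 229, 328 and 273. NSUN3 fell from 13.05 ± 0.34 to 4.95 ± 0.79 CPM in T98G, 2.64-fold lower (log2 -1.40, SE 0.15, edgeR adjusted p = 7.9e-05). In U251 NSUN3 fell from 15.4 ± 2.8 to 4.79 ± 0.48 CPM, 3.22-fold lower (log2 -1.69, SE 0.15, edgeR adjusted p = 2.3e-05). The NSUN3 effect did not differ detectably between lines (log2 difference -0.28, SE 0.21, edgeR adjusted p = 0.38).

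**Figure D1:**
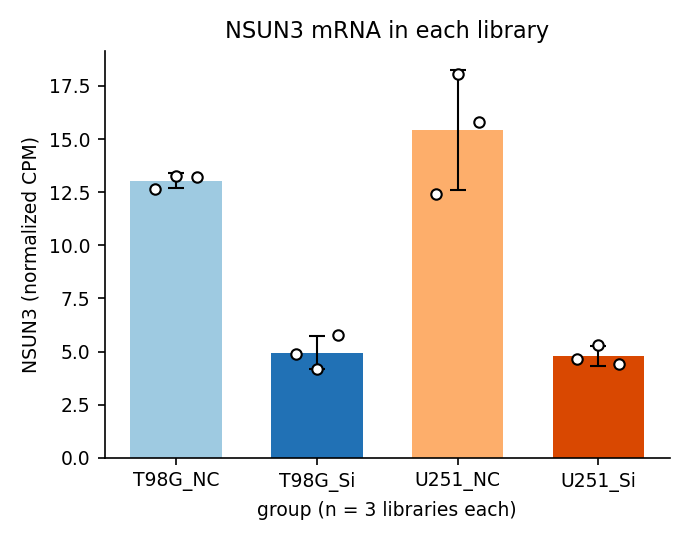
NSUN3 in normalized CPM in each of the 12 libraries by group, with the mean and SD of each group. The Si libraries lie between 4.19 and 5.77 CPM and the NC libraries between 12.4 and 18.0 CPM.

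On the first principal component of log2 CPM of all tested genes, which held 51.9% of the variance, T98G libraries lay between -32.8 and -25.3, and 4 of the U251 libraries between 28.7 and 35.6. U251_Si replicate 3, at 15.1, and U251_NC replicate 1, at 17.9, lay apart from the other U251 libraries toward T98G. Replicates of T98G correlated at 0.993 to 0.994 across genes, U251_NC at 0.988 to 0.994 and U251_Si at 0.983 to 0.990. Mitochondrial transcripts took 6.89% ± 0.721 of counts in T98G_NC and 6.47% ± 0.177 in T98G_Si, and 5.57% ± 0.161 in U251_NC and 5.89% ± 0.699 in U251_Si (SD, n = 3).

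**Figure D2:**
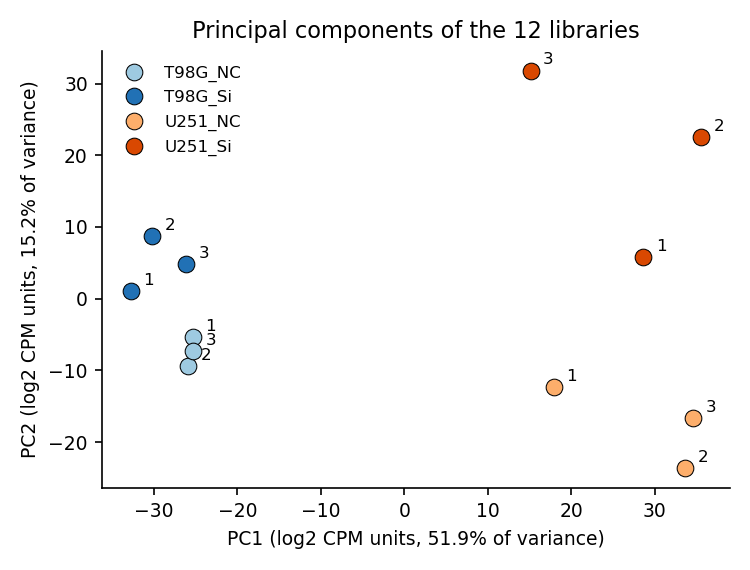
Scores of the 12 libraries on the first and second principal components of log2 CPM over all tested genes, with the percent of variance on each axis. The lines separate on the first component (51.9%), and U251_Si replicate 3 and U251_NC replicate 1 lie between the other U251 libraries and T98G.

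In T98G, enzymes of glycolysis and targets of the antioxidant factor NRF2 lay lower in Si as lists, by camera with the preset correlation. Lists of matrix genes and growth-factor response genes lay higher. None of these lists passed with an estimated correlation. Of 23 glycolysis genes 12 fell and none rose, among them LDHA, which makes lactate from pyruvate (3448 ± 170 to 2379 ± 75 CPM; log2 -0.54, SE 0.09, edgeR adjusted p = 0.0017), and the pyruvate kinase gene PKM (log2 -0.59, SE 0.11, edgeR adjusted p = 0.0039). PGK1, encoding phosphoglycerate kinase, fell by 0.45 on the log2 scale (edgeR adjusted p = 0.0071). Adjusted over the list alone, 16 members fell. The glycolysis list gave camera adjusted p = 7.2e-11 at a median log2 of -0.38, and adjusted p = 0.78 with an estimated correlation. Of 24 NRF2 targets 7 fell (16 adjusted over the list alone), including GCLC, the catalytic subunit for glutathione synthesis (log2 -0.73, SE 0.10, edgeR adjusted p = 0.00052), the heme oxygenase gene HMOX1 (log2 -0.62) and the pentose phosphate enzyme TALDO1 (log2 -0.44). The NRF2 list gave camera adjusted p = 1.0e-08 at a median log2 of -0.43, and adjusted p = 0.78 with an estimated correlation. The per-library score of the glycolysis list, its mean log2 deviation, was -0.55 to -0.48 in T98G_Si and -0.28 to -0.15 in T98G_NC. TALDO1 missed the threshold without T98G_Si replicate 1 or 2 or T98G_NC replicate 1 or 3 (highest edgeR adjusted p = 0.080).

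Among extracellular matrix and TGF-beta targets in T98G, 11 of 38 rose and none fell (13 adjusted over the list alone). The matrix list gave camera adjusted p = 1.0e-05 at a median log2 of 0.22, and adjusted p = 0.78 with an estimated correlation. The fibrillar collagen COL3A1 rose from 38.0 ± 6.9 to 73.9 ± 1.4 CPM (log2 0.96, SE 0.13, edgeR adjusted p = 0.00058), COL5A2 by 0.55 and the proteoglycan BGN by 0.99 on the log2 scale. Immediate early genes, switched on by growth signals, rose in 7 of 27 cases (8 adjusted over the list alone). The immediate early list gave camera adjusted p = 0.00023, and adjusted p = 0.78 with an estimated correlation. DUSP6, a phosphatase induced by ERK signaling, rose from 11.8 ± 0.83 to 23.0 ± 2.2 CPM (log2 0.96, SE 0.11, edgeR adjusted p = 0.00014), and the ETS factor ETV4 had a log2 of 1.14 and IER2 of 0.83. Replication-dependent histone genes, most of whose mRNA lacks a poly(A) tail, rose in 2 of 18 cases, HIST1H2BD (log2 0.85) and HIST1H2BJ (log2 1.14), and in 2 adjusted over the list alone. The histone list gave camera adjusted p = 0.00014 at a median log2 of 0.58, and adjusted p = 0.78 with an estimated correlation. With 1 T98G library left out the histone calls ended, HIST1H2BD for 4 of the libraries and HIST1H2BJ for 6 (highest edgeR adjusted p = 0.099 and 0.14), and BGN missed the threshold without T98G_NC replicate 3 (edgeR adjusted p = 0.053).

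Cytokines fell in 5 of 19 cases in T98G (7 adjusted over the list alone), including the chemokines CX3CL1 (log2 -0.98) and CXCL10 (log2 -1.06) and the macrophage growth factor CSF1 (log2 -0.49). The cytokine list gave camera adjusted p = 0.0027 at a median log2 of -0.49, and adjusted p = 0.78 with an estimated correlation. DNA replication genes fell in 4 of 35 cases (4 adjusted over the list alone), with RRM2, which makes deoxynucleotides, at log2 -0.78, UHRF1 at -0.47 and EXO1 at -0.53. The replication list gave camera adjusted p = 3.5e-05, and adjusted p = 0.86 with an estimated correlation. Subunits of respiratory complexes II to V lay lower as a list, although 0 of 39 members passed alone, over all genes or adjusted over the list alone. The complex II to V list gave camera adjusted p = 0.0043 at a median log2 of -0.13, and adjusted p = 0.86 with an estimated correlation. In the G2/M list 0 of 38 members passed under both adjustments. The G2/M list gave camera adjusted p = 0.031 at a median log2 of -0.12, and adjusted p = 0.86 with an estimated correlation, and missed the threshold without T98G_NC replicate 1 or 3 or T98G_Si replicate 2 (0.20, 0.28 and 0.27). Its scores overlapped between T98G_Si and T98G_NC. CSF1, CXCL10, UHRF1 and EXO1 each missed it without some single T98G libraries (highest edgeR adjusted p = 0.11, 0.082, 0.074 and 0.10). Interferon response genes did not pass as a list in T98G (0 higher and 1 lower of 40; camera adjusted p = 0.41).

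Single genes with large rises in T98G were CLEC7A, a receptor for fungal glucans (ENSG00000172243; chromosome 12, 10116777 to 10130258), which rose from 2.78 ± 0.81 to 14.8 ± 1.5 CPM (log2 2.41, SE 0.26, edgeR adjusted p = 0.00011), and the ETS factor ETV1, from 6.96 ± 0.95 to 19.8 ± 2.0 CPM (log2 1.51, SE 0.14, edgeR adjusted p = 3.2e-05). EDNRA, a receptor for endothelin, rose by 1.79, the tetraspanin TSPAN11 by 1.84 and the transcriptional repressor HIC1 by 1.55 on the log2 scale. DCN, a small proteoglycan, rose from 3.03 ± 0.85 to 8.62 ± 0.47 CPM. RGS4, a brake on G-protein signaling, rose by 2.00, HMOX2 by 2.82 (SE 0.66, edgeR adjusted p = 0.030), ADH1C by 1.97 (SE 0.51, edgeR adjusted p = 0.050) and LSM14A by 1.94 (SE 0.43, edgeR adjusted p = 0.016). HMOX2 held only 9 to 25 counts in T98G_NC and 75 to 155 in T98G_Si, and LSM14A 39 to 154 in T98G_Si. Left-out single libraries ended the calls of ADH1C (9 libraries, highest edgeR adjusted p = 0.16), HMOX2 (6, 0.12) and LSM14A (5, 0.074). Large falls were those of CTSS, a lysosomal cysteine protease (ENSG00000163131; chromosome 1, 150730196 to 150765957), from 66.7 ± 17 to 19.2 ± 1.4 CPM (log2 -1.79, SE 0.17, edgeR adjusted p = 6.7e-05), and the secreted Wnt-induced protein WISP1 (log2 -1.69). CDK15 (log2 -1.53), the adhesion receptor ADGRG2 (log2 -1.50), the proprotein convertase PCSK6 (log2 -1.44), TENM2 (log2 -1.39), the surface protein CD24 (log2 -1.31), CPA4 (log2 -1.25) and the microtubule protein MAP1A (log2 -1.21) fell as well. The naming rule required all 3 Si libraries of each of these genes to lie on one side of all 3 NC libraries, so this adds no support. Chance gives such a separation in 10% of unchanged genes. HMOX2, RGS4 and WISP1 had counts that scattered between replicates far above the trend of all genes in both lines.

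Across T98G, 896 genes changed, 452 higher and 444 lower in Si (122 of them at least 2-fold). With libraries scaled by their totals alone, 991 genes changed, 644 higher and 347 lower. Leaving out a single library moved the T98G count to 388, 480 or 500 without T98G_Si replicate 1, 2 or 3, to 409, 480 or 428 without T98G_NC replicate 1, 2 or 3, and to 1429 without U251_Si replicate 3, which enters through the shared spread. Fitted without U251, T98G gave 2861 genes, of which 882 were shared with the full fit.

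In U251, the interferon response rose in the Si libraries: 27 of 40 response genes were higher and none lower (30 adjusted over the list alone). The interferon list gave camera adjusted p = 3.3e-19 at a median log2 of 0.74, and adjusted p = 0.48 with an estimated correlation. ISG15, a ubiquitin-like protein induced by interferon (ENSG00000187608; chromosome 1, 1001138 to 1014540), rose from 50.9 ± 4.6 to 130 ± 16 CPM (log2 1.35, SE 0.10, edgeR adjusted p = 4.5e-06). MX1, an antiviral GTPase (ENSG00000157601; chromosome 21, 41420304 to 41459214), rose from 49.9 ± 12 to 180 ± 40 CPM (log2 1.85, SE 0.18, edgeR adjusted p = 0.00014), and IFITM1, which blocks viral entry and is not on the list, from 63.1 ± 13 to 228 ± 76 CPM (log2 1.86, SE 0.25, edgeR adjusted p = 0.0013). The 2-5A synthetases OAS1, OAS2 and OAS3 rose by 1.80, 1.71 and 1.51, RSAD2 by 1.97 and IFI6 by 1.69 on the log2 scale. The interferon score was 0.60, 0.62 and 1.17 in U251_Si replicates 1, 2 and 3, the last in a library that lies apart, and -0.21 to 0.07 in U251_NC. With both U251 libraries that lie apart left out, an alternative added after the data had been seen, 27 interferon genes were higher, and with no scaling beyond library totals 22 were.

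Genes for MHC class I presentation rose in 7 of 12 cases in U251 and 1 fell (8 and 1 adjusted over the list alone), among them HLA-C (563 ± 25 to 848 ± 57 CPM; log2 0.59, SE 0.07, edgeR adjusted p = 0.00029), HLA-B (log2 0.51) and the chaperone CALR (log2 0.61). The MHC class I list gave camera adjusted p = 0.00098 at a median log2 of 0.47, and adjusted p = 0.26 with an estimated correlation. Read placement on HLA genes, which vary widely between genomes, is uncertain.

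Genes of both ribosomes and of the respiratory chain were higher on average in U251_Si, each by a small amount. Cytosolic ribosomal proteins rose in 51 of 75 cases and none fell (58 adjusted over the list alone), with RPL39 at log2 0.48, RPL35 at 0.46 and RPL28 at 0.41. The ribosomal list gave camera adjusted p = 1.5e-14 at a median log2 of 0.30, and adjusted p = 0.61 with an estimated correlation. Subunits of complexes II to V rose in 18 of 39 cases (24 adjusted over the list alone), including COX6A1 (log2 0.54) and COX6C (log2 0.49) of cytochrome oxidase and ATP5MF (log2 0.58) of ATP synthase. The complex II to V list gave camera adjusted p = 3.1e-06 at a median log2 of 0.26, and adjusted p = 0.68 with an estimated correlation. Complex I subunits rose in 11 of 34 cases and 1 fell (15 and 1 adjusted over the list alone), with NDUFB7 at log2 0.42 and NDUFB11 at 0.36. The complex I list gave camera adjusted p = 0.00098, and adjusted p = 0.68 with an estimated correlation. Mitochondrial ribosomal proteins rose in 18 of 76 cases and 2 fell (23 and 2 adjusted over the list alone), such as MRPS34 (log2 0.41), MRPL58 (log2 0.44) and MRPS33 (log2 0.35). The mitochondrial ribosomal list gave camera adjusted p = 0.00075, and adjusted p = 0.68 with an estimated correlation. The ribosomal score was 0.19 in U251_Si replicate 3 and -0.15 in U251_NC replicate 1, the libraries that lie apart, and these were the highest of their groups (U251_Si from -0.11, U251_NC from -0.33). The complex II to V score was 0.19 and -0.11 in the same libraries, also the highest of their groups. U251_Si replicate 1 had -0.17, below U251_NC replicate 1, so these groups overlap, and the scores of complex I and of mitochondrial ribosomal proteins overlap in the same way. Mitochondrially encoded mRNAs did not pass as a list in U251 (1 of 13 higher; median log2 0.17, camera adjusted p = 0.093).

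Glioma mesenchymal state markers rose in 10 of 20 cases in U251 and 1 fell (12 and 1 adjusted over the list alone), among them the complement proteases C1S (log2 0.58) and C1R (log2 0.57) and the methyltransferase NNMT (log2 0.48). The mesenchymal list gave camera adjusted p = 0.00098, and adjusted p = 0.61 with an estimated correlation. Histone genes rose in 7 of 18 cases (9 adjusted over the list alone), with HIST1H2BD at log2 1.49, HIST1H2BK at 1.25 and HIST1H1C at 0.88. The histone list gave camera adjusted p = 0.00075 at a median log2 of 0.83, and adjusted p = 0.61 with an estimated correlation. Matrix genes rose in 11 of 38 cases and 2 fell (11 and 3 adjusted over the list alone), with the collagenase MMP1 at log2 1.52, COL1A2 at 0.61 and the integrin ITGB5 at 0.46. The matrix list gave camera adjusted p = 0.020, and adjusted p = 0.70 with an estimated correlation. Hypoxia-inducible genes rose in 5 of 21 cases and 1 fell (5 and 1 adjusted over the list alone), such as NDRG1 (log2 0.66), ANGPTL4 (log2 0.53) and the prolyl hydroxylase EGLN3 (log2 0.85). The hypoxia list gave camera adjusted p = 0.033, and adjusted p = 0.68 with an estimated correlation. NRF2 targets rose in 7 of 24 cases and 1 fell (8 and 1 adjusted over the list alone), with AKR1B10 at log2 0.91, PIR at 0.45 and TKT at 0.38. The NRF2 list gave camera adjusted p = 0.048, and adjusted p = 0.70 with an estimated correlation. G2/M genes fell in 12 of 38 cases and 2 rose (12 and 2 adjusted over the list alone), with HMMR at log2 -0.86, the cytokinesis proteins ANLN at -0.89 and ECT2 at -0.74. The G2/M list gave camera adjusted p = 0.020 at a median log2 of -0.13, and adjusted p = 0.70 with an estimated correlation. The histone score was highest of its group in both libraries that lie apart, at 0.29 in U251_Si replicate 3 (-0.37 and -0.40 in the others) and -0.44 in U251_NC replicate 1 (-1.02 and -1.06 in the others). The matrix score was lowest of its group in both, and at -0.15 U251_Si replicate 3 lay below all U251_NC libraries (-0.12 to 0.16). Scores of the hypoxia, NRF2 and G2/M lists overlapped between U251_Si and U251_NC too. These list calls were lost with 1 library left out: G2/M without U251_NC replicate 1 (0.20) or U251_Si replicate 1 (0.28), and matrix genes also without U251_Si replicate 2 (0.20, 0.21 and 0.081). Hypoxia genes lost theirs without the same 3 libraries (0.17, 0.18 and 0.078), and NRF2 targets without U251_NC replicate 1 or 2, U251_Si replicate 3 or T98G_Si replicate 2 (0.17, 0.056, 0.19 and 0.053). AKR1B10 missed the threshold without U251_NC replicate 2, and TKT without U251_NC replicate 1 or U251_Si replicate 2 (highest edgeR adjusted p = 0.056 and 0.093).

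**Figure D3:**
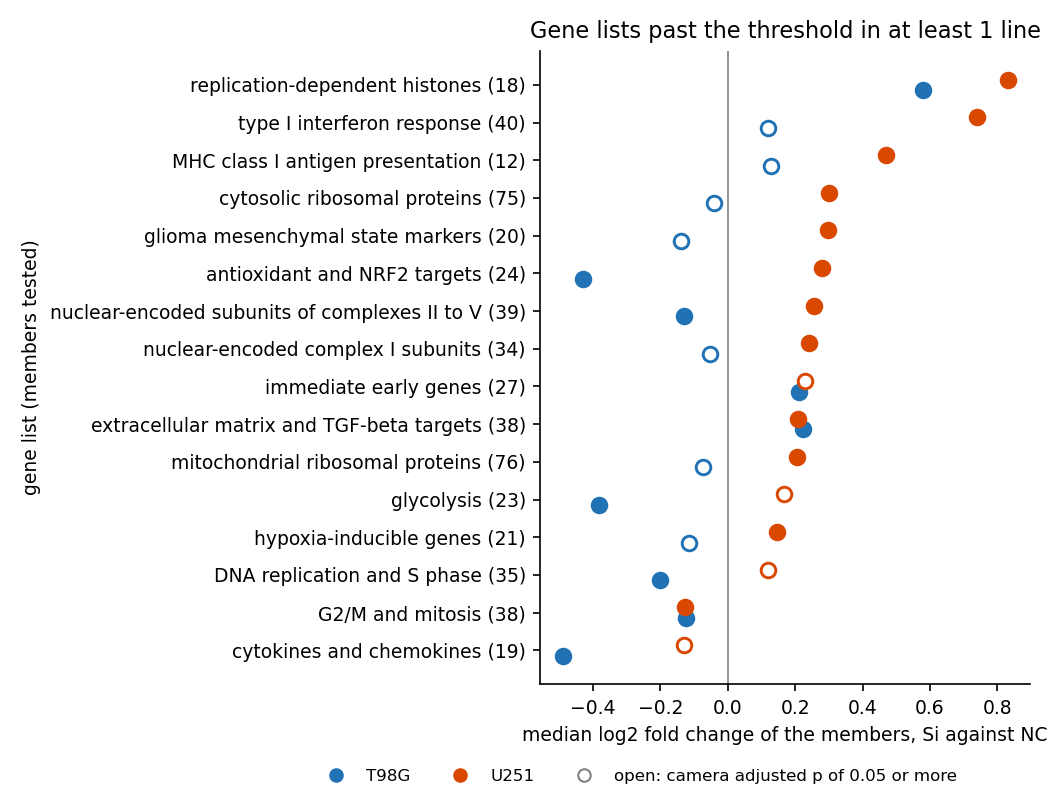
Median log2 fold change of the tested members of each gene list that passed camera, for Si against NC in T98G and in U251. The glycolysis list lies at -0.38 in T98G and the interferon list at 0.74 in U251.

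**Figure D4:**
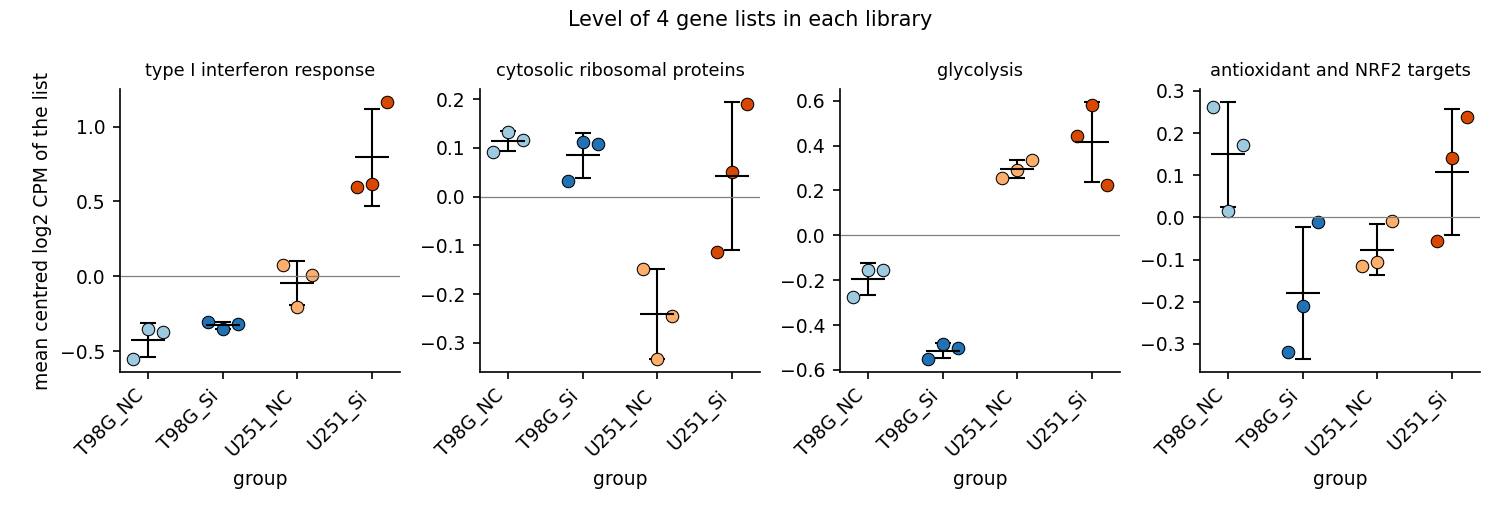
Score of gene lists in each library, the mean log2 deviation of the members, with 1 point per library and groups apart. The interferon score lies at 0.60 to 1.17 in U251_Si and at -0.21 to 0.07 in U251_NC.

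Single genes with large rises in U251 outside the interferon list were MMP3, stromelysin (13.7 ± 1.4 to 40.7 ± 10 CPM; log2 1.57, SE 0.18, edgeR adjusted p = 0.00024), the ribonuclease inhibitor RNH1 (log2 2.41, SE 0.67, edgeR adjusted p = 0.030) and VASN (log2 1.57, SE 0.50, edgeR adjusted p = 0.038). ANXA8, a phospholipid-binding annexin (ENSG00000265190; chromosome 10, 47460162 to 47484158), fell from 7.16 ± 0.24 to 1.85 ± 0.46 CPM (log2 -1.95, SE 0.25, edgeR adjusted p = 0.00029). Falls were also seen for the cytokine CSF2 (log2 -1.58), the protease ADAMTS6 (log2 -1.51), EVI2B (log2 -1.39), the apoptosis inhibitor BIRC3 (log2 -1.36), CPA4 (log2 -1.32) and HBEGF, a ligand of the EGF receptor (log2 -1.32). POLR3G, a subunit of RNA polymerase III, fell from 16.9 ± 0.60 to 6.77 ± 1.7 CPM (log2 -1.32, SE 0.15, edgeR adjusted p = 0.00014) and the transcription factor MYBL1 from 48.3 ± 5.3 to 19.4 ± 4.9 CPM (log2 -1.32, SE 0.16, edgeR adjusted p = 0.00024). RNH1, VASN, RSAD2, IFITM1, MX1, OAS1, IFI6, CSF2 and BIRC3 had counts scattered above the trend between replicates of both lines. Calls of ADAMTS6, BIRC3, CSF2, RNH1, VASN and IFI6 ended without 3, 3, 3, 5, 6 and 1 of the single libraries (highest edgeR adjusted p = 0.089, 0.10, 0.084, 0.10, 0.18 and 0.061). The size of the VASN rise rests on U251_Si replicate 2, without which the log2 was 0.61.

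Across U251, 3420 genes changed, 1607 higher and 1813 lower in Si (146 of them at least 2-fold). By library totals alone 3384 changed, 740 higher and 2644 lower. With U251_Si replicate 3 and U251_NC replicate 1 both left out, 3551 changed, 2120 higher and 1431 lower, of which 2706 were shared with the full fit. The U251 count dropped to 1649 without U251_Si replicate 2, 1765 without U251_NC replicate 2 and 2159 without U251_NC replicate 3. It was 665 when U251 was fitted without T98G, with 4 residual degrees of freedom in place of 8. T98G fitted alone, with as many, rose from 896 to 2861 genes, so the degrees of freedom alone do not explain the drop. Replicates scattered more in U251 (chi-square 5.80 to 42.1 per degree of freedom) than in T98G (5.35 to 9.25). The spread shared by both lines may thus be too small for U251, whose adjusted p-values may be too low, and too large for T98G.

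Both lines shared 170 genes higher in Si, against 58.1 expected from independent lists, and 137 genes lower, against 64.4, while 22 genes changed in opposite directions. Of the genes called in T98G, 74.4% had the same sign in U251, and the log2 fold changes correlated across genes at r = 0.246 (rho = 0.127), where genes are not independent replicates. CLEC7A rose in both lines (mean log2 2.16, SE 0.21, edgeR adjusted p = 1.9e-05), as did the matrix protein VIT (mean log2 1.31, SE 0.13, edgeR adjusted p = 1.3e-05), DCN (1.44), the channel regulator CLCA2 (1.30), the adhesion receptor ADGRF1 (1.09), HIST1H2BJ (1.17), ADH1C (2.04) and HMOX2 (2.65). ANXA8 fell in both (mean log2 -2.50, SE 0.20, edgeR adjusted p = 1.9e-06), with a log2 of -3.05 in T98G. CTSS (mean log2 -1.54, SE 0.12, edgeR adjusted p = 4.8e-06), TENM2 (-1.54), WISP1 (-1.46), CDK15 (-1.37), CPA4 (-1.29) and the Wnt antagonist DKK1 (-1.10) fell in both as well. Among the rises, U251 counts overlapped between groups for ADH1C (10 to 49 in U251_NC, 42 to 187 in U251_Si) and HMOX2 (4 to 25 and 22 to 107). U251_Si replicate 3, which lies toward T98G, held 5.99, 14.7 and 11.0 CPM of CLEC7A, CLCA2 and ADH1C. The U251 libraries of both groups that do not lie apart had means of 1.91, 6.46 and 1.92 CPM. The U251 rise of these genes thus leans in part on that library. The 170 genes higher in both lines became 97 or 87 without T98G_Si replicate 1 or 2 and 86, 96 or 92 without T98G_NC replicate 1, 2 or 3. The 137 genes lower in both became 76, 76 or 81 without T98G_Si replicate 1, 2 or 3, 82, 77 or 80 without T98G_NC replicate 1, 2 or 3, and 89 without U251_NC replicate 2.

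**Figure D5:**
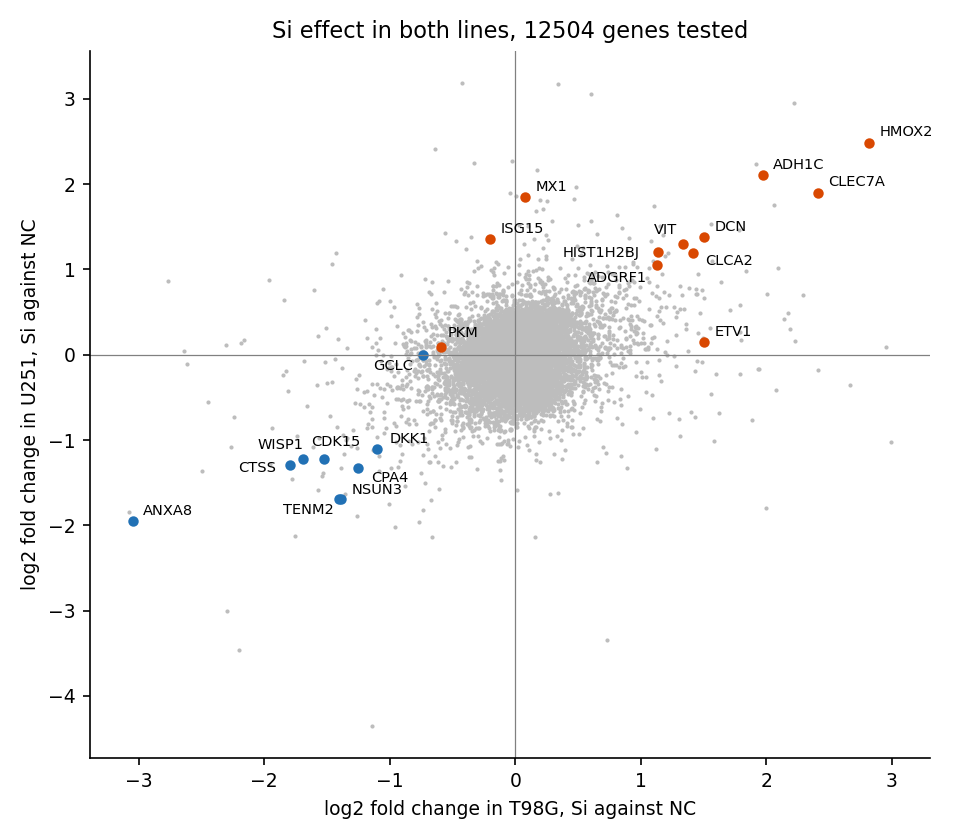
Log2 fold change of Si against NC in T98G (horizontal) and in U251 (vertical), with 1 point per tested gene. Genes called in the same direction in both lines (170 higher and 137 lower) lie in opposite corners, with NSUN3 at -1.40 and -1.69.

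Averaged over both lines, 2384 genes changed, 1247 higher and 1137 lower, and without T98G_Si replicate 2 the count was 1555. A list can pass on average through a single line. By camera with the preset correlation, the interferon, MHC class I and ribosomal lists passed in U251 but not in T98G. The immediate early and cytokine lists passed in T98G but not in U251. Interferon genes rose in 21 of 40 cases (27 higher and 1 lower adjusted over the list alone). The interferon list gave camera adjusted p = 2.9e-12, and adjusted p = 0.61 with an estimated correlation. Histone genes rose in 9 of 18 cases (12 adjusted over the list alone). The histone list gave camera adjusted p = 2.6e-06 at a median log2 of 0.67, and adjusted p = 0.61 with an estimated correlation. Matrix genes rose in 16 of 38 cases and 1 fell (18 and 1 adjusted over the list alone). The matrix list gave camera adjusted p = 1.8e-05, and adjusted p = 0.64 with an estimated correlation. Immediate early genes rose in 6 of 27 cases (6 adjusted over the list alone). The immediate early list gave camera adjusted p = 0.0045, and adjusted p = 0.64 with an estimated correlation. MHC class I genes rose in 4 of 12 cases (9 adjusted over the list alone), and ribosomal proteins in 11 of 75 (1 adjusted over the list alone). The MHC class I list gave camera adjusted p = 0.0026, and adjusted p = 0.34 with an estimated correlation. The ribosomal list gave camera adjusted p = 2.6e-06, and adjusted p = 0.71 with an estimated correlation. G2/M genes fell in 9 of 38 cases (11 adjusted over the list alone), and cytokines in 4 of 19 (5 adjusted over the list alone). The G2/M list gave camera adjusted p = 0.0028, and adjusted p = 0.71 with an estimated correlation. The cytokine list gave camera adjusted p = 0.045, and adjusted p = 0.64 with an estimated correlation, and was lost without T98G_NC replicate 2, T98G_Si replicate 1 or U251_Si replicate 3 (0.058, 0.065 and 0.095).

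By camera with the preset correlation, the effect of Si lay higher in U251 relative to T98G for the interferon, glycolysis, antioxidant and respiratory lists. None of these lists passed with an estimated correlation, and only part of their members passed singly. Interferon genes differed in 14 of 40 cases (21 adjusted over the list alone), with ISG15 at 1.56 (edgeR adjusted p = 0.00020), MX1 at 1.77 (SE 0.26, edgeR adjusted p = 0.012) and OASL at 1.63. The interferon list gave camera adjusted p = 1.2e-12 at a median log2 difference of 0.60, and adjusted p = 0.44 with an estimated correlation. CXCL10, a chemokine induced by interferon, had a log2 of -1.06 in T98G and 0.78 in U251 (difference 1.83, SE 0.30, edgeR adjusted p = 0.012). IFITM1, outside the interferon list, differed by 1.85 (SE 0.35, edgeR adjusted p = 0.029). Glycolysis genes differed in 12 of 23 cases (17 adjusted over the list alone), with LDHA at 0.60 (edgeR adjusted p = 0.027), PKM at 0.68 and PGK1 at 0.62. The glycolysis list gave camera adjusted p = 7.1e-10 at a median of 0.53, and adjusted p = 0.44 with an estimated correlation. NRF2 targets differed in 12 of 24 cases (15 adjusted over the list alone), with GCLC at 0.73 (edgeR adjusted p = 0.024) and TALDO1 at 0.74. The NRF2 list gave camera adjusted p = 1.6e-09 at a median of 0.62, and adjusted p = 0.44 with an estimated correlation. Complexes II to V differed in 8 of 39 cases (22 adjusted over the list alone) and cytosolic ribosomal proteins in 13 of 75 (40 adjusted over the list alone). The complex II to V list gave camera adjusted p = 1.1e-10, and adjusted p = 0.63 with an estimated correlation. The ribosomal list gave camera adjusted p = 1.4e-13, and adjusted p = 0.64 with an estimated correlation. In the other direction, the growth-response genes ETV1 (difference -1.36, SE 0.20, edgeR adjusted p = 0.0070) and DUSP6 (-1.21, edgeR adjusted p = 0.0050) had smaller effects in U251 than in T98G. LOXL4 (-1.63), FAP (-1.35), PDE4D (-1.35), LIFR (-1.40) and PARN (-3.79) had log2 values above 0 in T98G and below 0 in U251, and ACKR3 (1.72) and RAB11FIP3 (2.63) the reverse. PARN held 4 to 96 counts per library, and PARN, LIFR and RAB11FIP3 scattered between replicates of both lines. ACKR3, OASL, FAP, PDE4D and PARN missed the threshold without 10, 8, 8, 8 and 8 of the single libraries (highest edgeR adjusted p = 0.13, 0.094, 0.094, 0.092 and 0.11). IFITM1, LIFR and RAB11FIP3 missed it without 7 each and LOXL4 without U251_Si replicate 2 (highest edgeR adjusted p = 0.088, 0.087, 0.092 and 0.053).

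In all, 1167 genes differed in effect, 486 higher and 681 lower in U251 relative to T98G. By library totals alone 2256 differed, 205 higher and 2051 lower, and the median difference of all genes moved from 0.04 to -0.10 on the log2 scale. This count rested on single libraries of both lines: it was 32, 484 or 80 without T98G_Si replicate 1, 2 or 3, 35, 58 or 38 without T98G_NC replicate 1, 2 or 3, 2011, 58 or 49 without U251_NC replicate 1, 2 or 3, and 3397 or 22 without U251_Si replicate 1 or 2. It also rested on the model: with a replicate block 3 genes differed, and by DESeq2 2075.

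Among genes for intercellular bridges and mitochondrial traffic, connexin 43 moved in opposite directions in the lines and most others did not pass. GJA1, which encodes this gap junction protein, rose in T98G from 106 ± 8.3 to 156 ± 9.4 CPM (log2 0.56, SE 0.08, edgeR adjusted p = 0.00069) and fell in U251 from 98.7 ± 5.0 to 77.8 ± 4.1 CPM (log2 -0.34, SE 0.08, edgeR adjusted p = 0.0086), a difference of -0.90 (edgeR adjusted p = 0.0050). RHOT1, the adaptor that ties mitochondria to motors, fell in U251 (log2 -0.38, SE 0.08, edgeR adjusted p = 0.0051) and had a log2 of -0.06 in T98G (edgeR adjusted p = 0.70), but the difference missed the threshold (-0.31, edgeR adjusted p = 0.078). TNFAIP2, which starts tunneling nanotubes, had a log2 of 0.03 in T98G and 0.04 in U251, MYO10 0.06 and -0.10, the actin bundler FSCN1 -0.12 and 0.18, and RALA 0.05 and -0.06, none past the test. Of 38 nanotube and protrusion genes 2 rose and 1 fell in T98G (4 and 4 adjusted over the list alone; camera adjusted p = 0.87), and 5 rose and 10 fell in U251 (5 and 11 adjusted over the list alone; camera adjusted p = 0.29), where the median was 0.04, the mean -0.04 and the test downward. RAB11FIP3, also on that list, had a log2 of -1.43 in T98G (edgeR adjusted p = 0.056) and 1.20 in U251 (edgeR adjusted p = 0.046). Its difference was 2.63 (edgeR adjusted p = 0.031), with counts that scattered between replicates of both lines. In the mitochondrial transport list of U251, 6 of 24 fell, including the kinesin KIF5B (log2 -0.62) and the fission and fusion GTPases DNM1L (-0.47) and OPA1 (-0.47), and the list did not pass (camera adjusted p = 0.093). KIF5B, DNM1L and OPA1 were chosen after their values were seen.

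CD274, the checkpoint ligand PD-L1, fell in U251 (5.54 ± 1.1 to 3.47 ± 0.51 CPM; log2 -0.68, SE 0.18, edgeR adjusted p = 0.016) and had a log2 of -0.44 in T98G (edgeR adjusted p = 0.26), and the difference did not pass (-0.24, edgeR adjusted p = 0.60). Among mitochondrial transcripts, MT-CO1 had a log2 of -0.13 in T98G and 0.17 in U251, MT-ND1 -0.06 and 0.27, MT-CYB -0.06 and 0.34 and MT-ATP6 -0.04 and 0.17, and none passed. ATF4, the factor of the integrated stress response, rose in U251 (log2 0.30, SE 0.09, edgeR adjusted p = 0.028) and had a log2 of -0.00 in T98G. CD274 missed the threshold without U251_NC replicate 2 or 3, and ATF4 without U251_NC replicate 1 or 3 or U251_Si replicate 2 (highest edgeR adjusted p = 0.079 and 0.094). DDIT3 (0.25 and 0.47) and GDF15 (0.45 and -0.00) did not pass in T98G or U251, and GAP43 had too few counts to test.

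Between the NC libraries, U251 held far more transcripts of inflammatory signaling than T98G and fewer of ribosomes and respiration. CXCL8, a chemokine for neutrophils (ENSG00000169429; chromosome 4, 73740506 to 73743716), stood at 3.92 ± 0.94 CPM in T98G_NC and 166 ± 67 CPM in U251_NC, 42.5-fold higher (log2 5.41, SE 0.80, edgeR adjusted p = 0.0010). CSF2 (log2 3.93), IL6 (3.65), CXCL3 (3.52), the tight junction protein CLDN1 (3.84) and the retinal reductase DHRS3 (4.10) were higher in U251, and PI15 (-3.74), RGS2 (-3.60), MMP3 (-2.96), CBLN2 (-2.96), COL14A1 (-2.95) and PRPF31 (-2.74) lower. NF-kB targets were higher in 23 of 26 cases and lower in 1 (23 and 1 adjusted over the list alone). The NF-kB list gave camera adjusted p = 2.7e-13 at a median log2 of 1.28, and adjusted p = 0.42 with an estimated correlation. Cytosolic ribosomal proteins were lower in 65 of 75 cases (65 adjusted over the list alone, camera adjusted p = 2.4e-13) and complexes II to V in 31 of 39 (33 adjusted over the list alone, camera adjusted p = 3.0e-10), both with adjusted p = 0.42 with an estimated correlation. In total 5235 genes differed, 2672 higher and 2563 lower in U251 (719 at least 2-fold). By library totals alone 5227 differed, 3175 higher and 2052 lower. CXCL8, IL6, CXCL3, CLDN1, CSF2, PI15, RGS2 and PRPF31 scattered between replicates, and PRPF31 missed the threshold without any of 8 single libraries (highest edgeR adjusted p = 0.12).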

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

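The tests of the interferon genes, of scattered counts, and of mixing and exchanged labels in the libraries that lie apart were chosen only after those results were seen; the splits of the libraries and the comparison of depth were planned.

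Results in this part were picked out because the effect of Si differed between U251 and T98G by a test of the difference itself. Such a difference passed for 1167 genes, 486 higher and 681 lower in U251 relative to T98G, a count that fell to 22 without U251_Si replicate 2 and rose to 3397 without U251_Si replicate 1. Of the 100 splits of the libraries within lines and their mirrored sums, 200 in all, 2 gave as many genes. These were the real split and its mirror, in which the effects of the lines are added in place of subtracted (2384 genes). The next highest gave 959. The splits ask whether the labels matter at all, not whether both lines responded alike. They therefore cannot exclude chance for a difference between lines. The count also depends on the model (3 genes with a replicate block, 2075 by DESeq2). For the mean over lines 1 of 200 gave as many as the real 2384, with 1167 as the highest other.

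Large differences toward U251 were RAB11FIP3 (2.63), IFITM1 (1.85), CXCL10 (1.83), MX1 (1.77), ACKR3 (1.72) and OASL (1.63), and toward T98G PARN (-3.79), LOXL4 (-1.63), LIFR (-1.40), ETV1 (-1.36), FAP (-1.35) and PDE4D (-1.35), all log2. IFITM1, CXCL10, MX1 and OASL are induced by interferon, and LOXL4 and FAP act on the extracellular matrix. Among gene lists the median log2 difference was 0.62 for NRF2 targets, 0.60 for interferon genes, 0.53 for glycolysis, 0.39 for DNA replication and 0.39 for mesenchymal markers. It was 0.38 for complexes II to V, 0.33 for cytosolic ribosomal proteins, 0.30 for mitochondrially encoded mRNAs, 0.30 for mitochondrial ribosomal proteins, 0.29 for hypoxia genes, 0.28 for complex I and 0.20 for the proteasome. All 12 lists lay higher in U251 relative to T98G by camera with a preset correlation and none passed with an estimated correlation. The mitochondrially encoded and proteasome lists each missed the threshold without 2 of the single libraries (highest camera adjusted p = 0.14 and 0.067).

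Interferon response genes were higher in U251_Si. The tables argue against scaling as the whole cause, since 22 interferon genes were still higher with no scaling beyond library totals, and against the libraries that lie apart, since 27 were higher with both left out. Leukocytes in the culture are argued against by 15 microglia and macrophage markers, whose summed CPM was 11.9 ± 1.65 in U251_Si and 12.0 ± 0.132 in U251_NC, a difference of -0.0124, led by ITGAM. What stays open is whether lower NSUN3 itself or the reagent that lowered it raised these genes, which the design does not separate. IFNB1 held 0 to 2 counts per library, too few to compare.

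Genes with erratic counts numbered 249, with 176 outside the fixed lists. In both lines the log2 of their SD between replicates lay at least 1 above the trend for genes of like expression. This is a ratio of spreads and not the size of the scatter itself. HMOX2, RNH1 and PARN are among those named here. Near-identical copies as the whole cause are argued against, since 11.9% of the 176 share over 20% of their sequence with another gene, although this is more than the 6.22% of other genes, so a part is not excluded. Overlap on the same strand is argued against too, seen for 3.41% (7.88% of other genes). A candidate explanation is loss of reads at loci that recur in alternative sequences of the genome build, which puts such genes side by side: 23 neighbouring pairs were found, against at most 11 in 10000 random draws. Neighbours under shared regulation would also form pairs, and the alternative sequences were not examined, so the cause stays open.

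U251_NC replicate 1 and U251_Si replicate 3 lay toward T98G on the first principal component. Mixed-in T98G RNA as the whole cause is argued against: of 31 genes at least 4-fold lower in the other U251 libraries, 14 and 9 lay below the limit set by the needed shares of 25.03% and 29.6%, where 2.5% were expected, although smaller shares (median 5.53% and 15.7%) are not excluded. These limits and shares came from means that pool Si and NC libraries, so genes changed by Si shift them. MMP3, higher in U251_Si, stood at 12.1 CPM in U251_NC replicate 1 against a pooled 29.5 CPM. Such genes count against mixing in an NC library without bearing on it. An exchange of the labels of both libraries is argued against by NSUN3, at 12.4 CPM in the library labelled U251_NC replicate 1. Of total counts, genes detected and mitochondrial share, 0 lay outside the range of the other U251 libraries on the same side in both. The share of counts in the 10 highest genes did, at 9.38% and 9.57% against 9.62% to 10.9% in the other U251 libraries; the T98G libraries had 10.2% to 12.5%, so this is not a move toward T98G. Culture state or density was not tested and stays open.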

How the results depend on the processing

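The settings without scaling and with a pair of U251 libraries left out were chosen after the data had been seen. NSUN3 kept its direction and call in every setting (log2 -1.52 to -1.29 in T98G and -1.81 to -1.54 in U251 with 1 library left out). Of 3726 combinations of 140 called named genes with settings, 3445 kept direction and call, 281 missed the threshold and 0 reversed. Where no cause is given below, the cause was not tested. Depth limits low genes: HMOX2 and PARN rest on under 100 counts in most libraries.

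Counts of changed genes moved with the samples that set the spread. With each line fitted alone T98G gave 2861 genes (882 shared with the full fit) and U251 665 (664 shared), with 4 residual degrees of freedom. With U251_Si replicate 3 and U251_NC replicate 1 both left out T98G gave 2003 (892 shared), the difference between lines 2636 (1099 shared) and 354 genes were higher in both lines. A minimum log2 fold of 1 left 122, 146, 96, 99 and 719 genes for T98G, U251, the difference, the mean and the NC libraries, and 12 and 19 higher and lower in both lines, by construction. The difference between lines gave 2256 genes without scaling, 2075 by DESeq2, and 2146 and 2117 by limma-trend on FPKM with pseudocounts of 1 and 0.1. Without a filter on low counts the correlation of both lines' effects was 0.0532, as low genes entered.

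With a replicate block T98G gave 497 genes (482 shared), U251 2262 (2231 shared), the difference between lines 3, genes higher in both lines 96 and lower in both 82, and 120 of the 140 named calls passed. The labels do not say whether the replicate numbers pair Si and NC libraries. Deviations of same-numbered libraries correlated at -0.08, 0.04 and 0.02 in T98G and -0.20, 0.11 and -0.13 in U251. With so few libraries per group these values cannot decide whether the libraries are paired, and the block takes up residual degrees of freedom. It changed no other count by over 1.5 times.

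No gene list passed with an estimated correlation: 0 in each of the 5 contrasts, against 9, 12, 12, 8 and 21. By fry's directional test, which asks whether a list's genes move one way, 3 lists passed in T98G, 13 on average and 35 between NC libraries, and by its mixed test 22, 39, 30, 36 and 40.

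Uncalled panel genes crossed 0. In T98G MT-ATP6 (-0.04) was 0.0103 without scaling and 0.0173, 0.0173 and 0.0173 by FPKM with pseudocounts of 1 and 0.1 and without a filter, and ATF4 was 0.00499 with upper-quartile factors, 0.0452 without scaling, 0.0382, 0.0384 and 0.0382 by FPKM and 0.00154 with both U251 libraries out. In U251 TNFAIP2 (0.04) was -0.0584 without scaling and -0.0581, -0.0611 and -0.0581 by FPKM, MYO10 (-0.10) was 0.0137 with both libraries out, and GDF15 was 0.00782 without a filter, 0.0942 by voom, 0.0764 with the replicate block and 0.10 by CPM.

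With 1 library left out counts ran from 388 to 1429 in T98G, 1649 to 4613 in U251, 22 to 3397 for the difference, 1555 to 3437 for the mean, 3801 to 5993 between NC libraries, 86 to 247 higher and 76 to 185 lower in both lines, and the correlation from 0.180 to 0.274. Lists past camera ran from 8 to 11, 10 to 15, 11 to 14, 8 to 12 and 17 to 21. In T98G ATF4 ran from -0.0711 to 0.10, DDIT3 -0.12 to 0.44, GDF15 -0.24 to 0.86, MT-ATP6 -0.12 to 0.0833, MT-CYB -0.12 to 0.0391 and MT-ND1 -0.13 to 0.0476, and in U251 GDF15 -0.32 to 0.29, MYO10 -0.17 to 0.0128 and TNFAIP2 -0.0673 to 0.11.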

Other observations

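All tests of pathway terms and the naming of single genes in this part were chosen after results had been seen; the marker lists and the splits of libraries were planned.

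Pathway terms carried by the deposited table were tested as well. How far their members overlap the fixed lists, such as the histone and NRF2 lists, was not counted, so they are not separate evidence. A term names a set of genes, and a disease term does not mean that the disease process changed. Of 246 terms with 10 to 150 tested genes, glutathione metabolism was lower in T98G_Si (7 of 36 genes lower and none higher, camera adjusted p = 0.00013), and adjusted p = 0.99 with an estimated correlation. In U251_Si the term for metabolism of xenobiotics by cytochrome P450 was higher (7 of 29 genes higher and 0 lower, camera adjusted p = 0.022), as were galactose metabolism (10 higher and 1 lower of 21, camera adjusted p = 0.048) and PPAR signaling (6 of 18 higher, camera adjusted p = 0.048). These gave adjusted p = 1.00 with an estimated correlation. The pentose phosphate pathway, which makes NADPH and ribose, differed between lines, higher in U251 relative to T98G in 8 of 23 genes (camera adjusted p = 0.014), and adjusted p = 0.99 with an estimated correlation. The term for systemic lupus erythematosus was higher on average over both lines (14 higher and 2 lower of 43, camera adjusted p = 0.023), and adjusted p = 0.98 with an estimated correlation.

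Of 17 tested writers, erasers and readers of 5-methylcytosine 2 fell in U251, NSUN3 and TRDMT1 (log2 -0.83, edgeR adjusted p = 0.0062), and the list did not pass (camera adjusted p = 0.12). Checkpoint ligands moved both ways in U251, 6 higher and 2 lower of 21 (camera adjusted p = 0.33), with LGALS9, encoding galectin 9, at log2 0.73 (edgeR adjusted p = 0.0030) and CD47, a signal that inhibits phagocytosis, at -0.46 (edgeR adjusted p = 0.0013). CD47 was also lower in T98G (log2 -0.34, edgeR adjusted p = 0.013). TRDMT1, LGALS9 and CD47 were chosen after their values were seen.

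Between the NC libraries, further lists were higher in U251 by camera: immediate early genes (19 of 27 higher, 21 adjusted over the list alone, camera adjusted p = 3.0e-10), G2/M genes (26 of 38 higher and 1 lower, 29 and 1 adjusted over the list alone, camera adjusted p = 8.4e-10) and integrated stress response targets (25 of 35 higher and 1 lower, 26 and 1 adjusted over the list alone, camera adjusted p = 1.2e-07). Mitochondrial ribosomal proteins were lower (40 of 76 lower and 2 higher, 44 and 3 adjusted over the list alone, camera adjusted p = 6.0e-07), as were histone genes (9 of 18, 11 adjusted over the list alone, camera adjusted p = 7.3e-06). Over the 21 lists past camera the adjusted p ran from 0.42 to 0.54 with an estimated correlation.

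Markers of other cells were listed in part. Of the T and B cell list 7 of 15 genes were listed, led by IL7R, at 18.6 to 32.1 CPM in T98G, 68.9 to 76.2 CPM in U251_NC and 22.4 to 47.9 CPM in U251_Si, and of the microglia and macrophage list 15 of 18, led by ITGAM (3.54 to 7.41 CPM). The endothelial and pericyte list had 11 of 12 listed, led by FLT1 (2.84 to 7.74 CPM), and the oligodendrocyte list 7 of 9, led by CNP. Neuron markers, 10 of 12 listed and led by MAP2, had 0 of 6 tested members changed in T98G and 1 lower in U251 (camera adjusted p = 0.95 and 0.35). The other marker lists had fewer than 5 tested members and got no list test.

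Splits of the libraries bear on chance. With 3 libraries against 3, the 10 splits are too few for a share under 0.05: in T98G the real split gave 896 genes and the highest other 0, in U251 3420 and 4, and between the NC libraries of the lines 5235 and 0, so 1 split of 10 reached the real count in each. The correlation of the effects of both lines across genes, 0.246, was reached in size by 3 of 100 splits within lines, the real one included. The 2 other splits gave values larger in size (0.295 and -0.280), each with only 1 line split as labelled. A correlation of this size can thus arise with wrong labels in 1 line, so chance is not excluded. Without a filter on low counts, a setting the splits did not cover, the correlation was 0.0532.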
